A study of Mus musculus with 21 samples.

How the data were processed

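RNA from the right lung of male C57BL/6 mice was measured on 21 Affymetrix arrays with 1 biotin-labelled sample each, per the labels. The deposited table holds 1 log2 value per probe set and array, made by the authors with RMA (robust multi-array averaging, which corrects background, normalizes between arrays and summarises probes), per the submitters' processing notes; the version and settings of RMA are not given in the sources used here. The table holds 35556 probe sets with no column outside the 21 samples, and no 2 columns were identical. Values ran from 2.98 to 14.1 over all arrays, with array medians from 5.98 to 6.18 and correlations between arrays of 0.964 to 0.997. The file carries no detection call, so dim genes were kept in the main analysis and left out only in an alternative. The labels' protocols describe amplification from the 3' end, whereas the probe annotation is that of a whole-transcript mouse gene array. Which labelling chemistry was used stays unsettled; the protocol text is identical for all 21 samples.

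Gene names came from the platform annotation, which gave 1 symbol for 21789 probe sets, several for 1621 and none for 12146. A mouse gene table of assembly GRCm38.p6 was used for names only, and matched the gene number of 21698 of the single-symbol probe sets; no coordinates are printed because the deposited file gives no build. Of the 19938 genes, 999 had over 1 probe set and were represented by the probe set with the highest mean over all arrays. Cross-hybridisation between closely related genes was not checked, so values of Cyp4a12b, Hspa1a, Chil4, Ifi208 and Ifi209, which have near-identical relatives, are uncertain as to the copy.

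Each of the 7 conditions had 3 arrays, 1 for each of 3 regions: the medial lobe (replicate 1), the cardiac lobe (replicate 2) and the whole right lung (replicate 3). A linear model with additive terms for condition and region was fitted to all 21 arrays with limma 3.58.1 in R 4.3.3, followed by empirical Bayes moderation, leaving 12 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison, over all 19938 genes. The comparisons were each later condition against day 0, day 56 after pneumonectomy against day 56 after sham surgery, each day against the day before it in the course, the cardiac against the medial lobe, the mean of both lobes against the whole lung, and a moderated F test of any difference among conditions. Because each region had 1 array per condition, the difference in early response between the lobes was tested on region by phase means, with day 0 and sham as control, days 3 and 7 as early, and days 14, 28 and 56 as late. All adjusted p-values of genes in the text come from these limma models, and errors after ± are standard errors of the fitted difference unless SD is stated.

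A total of 38 gene lists of pathways, processes and cell types was fixed before the data were examined, as were the comparisons, the rule for named genes and all but 2 kinds of alternative processing. Lists were tested with camera from limma at a preset correlation of 0.01, adjusted over the 532 tests of 38 lists in 14 comparisons, and again with the correlation estimated from the data. Of the 532 tests, 229 passed with the preset value and 1 with the estimated value, that of the heat shock list at day 56 between pneumonectomy and sham. Members were also counted from the gene tests, over all genes and adjusted over the list alone.

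Named genes followed a fixed rule. For days 3 and 7 against day 0 and for the cardiac against the medial lobe, these were the 8 largest rises and 8 largest falls among genes that passed and had 1 sign in all 3 regions, or in at least 6 of 7 conditions for the lobes. For other comparisons the 3 largest of each were taken, all that passed if fewer did, and if none passed the 3 smallest p-values. Predicted genes, with symbols starting with Gm or ending in Rik, were passed over. From each list described, up to 4 passing members were taken by size, or if none passed the 2 with the smallest p. Genes outside this rule are said to have been chosen after their values were seen.

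The procedure was tested on simulated data with 100 genes shifted by log2 0.5 and 100 by log2 1 among 19938. It recovered 45 and 93 of them for day 3 against day 0, 62 and 92 for day 7, 48 and 95 for day 28, and 11 and 63 for the difference in early response between the lobes. None had the wrong sign, and 9, 6, 6 and 8 unchanged genes were called in these comparisons. The simulated noise was independent between genes and arrays, without effects shared by the arrays of a condition. Recovery in the real data may therefore differ. The alternatives chosen in advance were no region term, every probe set or the mean of a gene's probe sets, leaving out the dimmer genes, a prior with trend and robust moderation, centring each array on its median, the lobes alone, leaving out each array in turn, only the 6 arrays compared, and the mean of day 0 and sham as control. Leaving out the day 7 cardiac lobe and day 56 pneumonectomy whole lung arrays, and using sham as the control for earlier days, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No sample was left out of the main analysis.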

Results

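Gene expression was measured in the right lung of mice after removal of the left lung (left pneumonectomy), an operation after which the remaining lobes grow. The 21 arrays covered 7 conditions: day 0 before surgery, days 3, 7, 14, 28 and 56 after pneumonectomy, and day 56 after sham surgery. Each condition held 1 array of the medial lobe, 1 of the cardiac lobe and 1 of the whole right lung (n = 3 arrays per condition). The title of the series asks whether growth passes through a phase of lost differentiation and a phase of renewed development. The labels do not say whether the regions of a condition came from the same or from pooled animals, and the whole lung may include the same lobes. The p-values rest on the spread left after the condition and region terms, that is, on how far changes differ between regions. This spread may be partly technical, and the number of arrays limits the precision. If the regions of a condition shared animals, differences between animals would add to the condition differences and would not be measured by the p-values.

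Small RNA levels and the spread of values differed between arrays. The mean log2 value of 60 small RNA genes (small nucleolar, Cajal body and spliceosomal RNAs) was 8.51 ± 0.70 (SD, n = 7) in the whole lungs, 7.15 ± 0.14 (SD, n = 7) in the medial lobes and 7.27 ± 0.43 (SD, n = 7) in the cardiac lobes. The day 7 cardiac lobe array (8.11, interquartile range 3.55) and the day 56 pneumonectomy whole lung array (9.77, interquartile range 3.39) had the highest small RNA mean and the lowest interquartile range of their regions. By the gap to the next array of the region, only the interquartile range of the day 7 cardiac lobe lay beyond the critical value of a Dixon test. Counts are also given without these 2 doubted arrays, which were chosen after seeing the data.

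**Figure D1:**
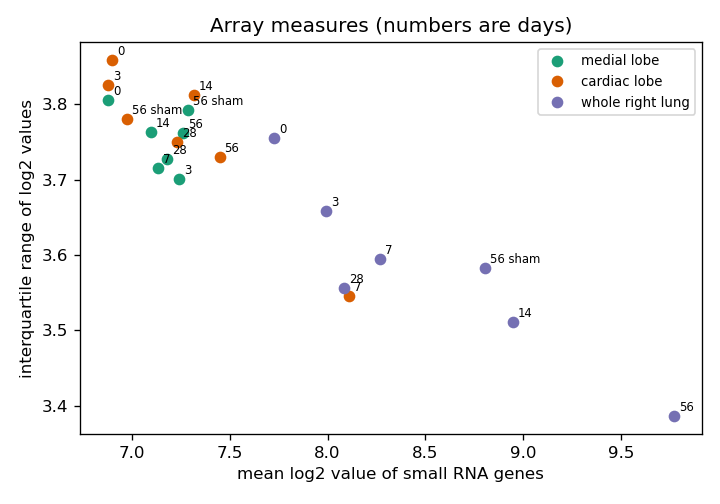
Mean log2 RMA value of 60 small RNA genes (x axis) against the interquartile range of all log2 values (y axis), 1 point per array, coloured by region and numbered by day. The whole lungs lie to the right of most lobes, and the day 7 cardiac lobe array, at 8.11 and 3.55, lies among them.

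Across the 7 conditions 1547 of 19938 genes differed (moderated F test, smallest adjusted p = 4.21e-07). The largest departure from day 0 was then sought among the days after pneumonectomy, with sham left out. For 606 of these genes it was a higher value at day 3 and for 232 a lower value at day 3. A higher value at day 7 was the largest departure for 141 genes and a lower one for 250. Day 28 gave the largest departure for 5 genes upward and 19 downward. Without the region term the F test passed 671 genes, and without the 2 doubted arrays it passed 2501.

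**Figure D2:**
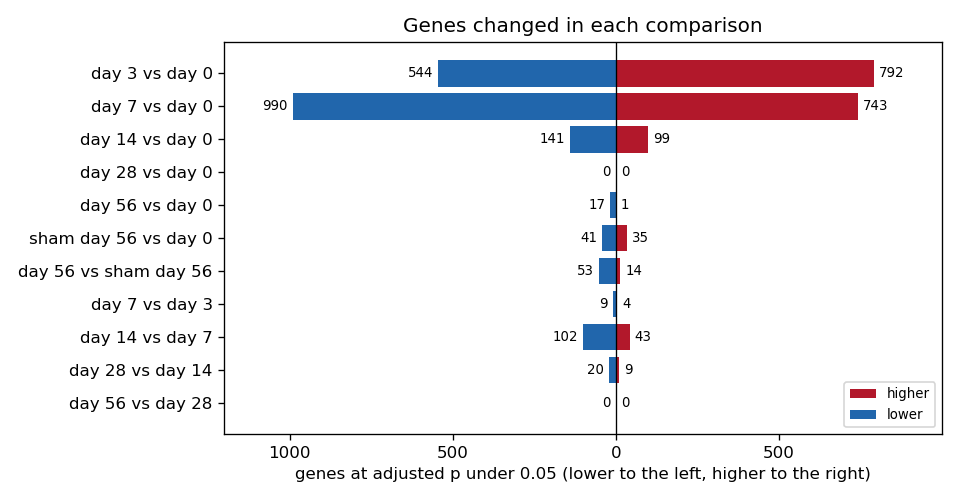
Number of genes at an adjusted p under 0.05 in each comparison between conditions (limma, 19938 genes), with genes lower to the left and higher to the right. Day 3 had 792 higher and 544 lower, day 7 had 743 higher and 990 lower, and day 28 had none in either direction.

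The 8 genes that rose most at day 3 after pneumonectomy were Saa3, Prg4, Arg1, Serpinb2, Timp1, Cd5l, Clec4e and Cxcl2. Saa3, an acute-phase serum amyloid, rose from 6.77 ± 0.29 to 12.07 ± 0.38 (log2, SD, n = 3), a 39.4-fold difference. Prg4, the joint and mesothelial lubricant lubricin, rose 25.6-fold, Arg1, the arginase of alternatively activated macrophages, 20.3-fold. Serpinb2, an inhibitor of plasminogen activators, rose 17.2-fold and Timp1, an inhibitor of matrix metalloproteinases, 11.4-fold. Cd5l, a macrophage scavenger protein, Clec4e, a C-type lectin receptor of myeloid cells, and Cxcl2, a neutrophil chemoattractant, rose by log2 2.99 ± 0.57, 2.88 ± 0.59 and 2.70 ± 0.62. The 8 largest falls were those of Cyp4a12b (a fatty acid hydroxylase, log2 -1.66 ± 0.40), Depp1 (-1.43 ± 0.35), Lrat (retinol esterification, -1.37 ± 0.33) and Cxcl9 (an interferon-induced chemokine, -1.34 ± 0.28), followed by Ifi208 (-1.33 ± 0.27), Bex4 (-1.25 ± 0.15), H2-Eb2 (an MHC class II chain, -1.18 ± 0.25) and Cd69 (a lymphocyte activation marker, -1.15 ± 0.27). With sham as the control, Cxcl9 lay at 0.40 instead.

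Of 29 measured mitosis genes, 28 rose at day 3, among them Plk1 (mitotic kinase, log2 1.95 ± 0.20), Ccna2 (cyclin A2, 1.93 ± 0.25), Prc1 (1.86 ± 0.23) and Kif20a (1.77 ± 0.28). Adjusted over the list alone 28 rose. The list passed with adjusted p = 1.09e-35, and had adjusted p = 0.166 with an estimated correlation. Of 27 DNA replication genes 18 rose, 25 adjusted over the list alone, led by Rrm2 (ribonucleotide reductase, 1.36 ± 0.20) and Tk1 (thymidine kinase, 1.15 ± 0.16). That list passed with adjusted p = 1.24e-18, and adjusted p = 0.166 with an estimated correlation. In the lobes alone, with fewer arrays, 10 mitosis, 2 DNA replication, 7 matrix, 5 acute inflammation, 3 monocyte and 8 mesothelial genes rose, and 2 T and NK cell and 2 B and plasma cell genes fell.

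Of 26 fibrillar and elastic matrix genes 13 rose, 19 adjusted over the list alone, including Timp1 (3.52 ± 0.23), the collagen I chains Col1a1 (2.12 ± 0.40) and Col1a2 (1.94 ± 0.40), and Col3a1 (1.88 ± 0.38). The list's adjusted p was 1.99e-16, and adjusted p = 0.146 with an estimated correlation. Of 17 acute inflammation genes 11 rose, 14 adjusted over the list alone, Saa3, Timp1, Cxcl2 and the monocyte chemoattractant Ccl2 (2.37 ± 0.36) among them (adjusted p = 7.26e-14, and adjusted p = 0.166 with an estimated correlation). Of 13 monocyte and interstitial macrophage genes 7 rose, 11 adjusted over the list alone, with Arg1 and the complement genes C1qc (1.71 ± 0.33), C1qa (1.69 ± 0.28) and C1qb (1.67 ± 0.22) in front (adjusted p = 1.37e-09, and adjusted p = 0.166 with an estimated correlation). Of 12 mesothelial genes 8 rose, 9 adjusted over the list alone, including Wt1 (a transcription factor of mesothelium, 1.36 ± 0.16), Aldh1a2 (retinoic acid synthesis, 0.81 ± 0.11), Muc16 (0.75 ± 0.20) and Bnc1 (0.69 ± 0.18). The mesothelial list had adjusted p = 3.47e-09, and adjusted p = 0.146 with an estimated correlation.

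Lymphocyte lists stood lower at day 3. Of 14 T and NK cell genes 7 fell, 13 adjusted over the list alone, led by Cd3g (a T cell receptor subunit, -1.13 ± 0.18) and Ccr7 (a homing receptor, -1.05 ± 0.19). Its test gave adjusted p = 8.01e-11, and adjusted p = 0.166 with an estimated correlation. Of 12 B and plasma cell genes 8 fell, and 8 adjusted over the list alone, led by Ms4a1 (CD20, -1.11 ± 0.23) and Cr2 (-1.01 ± 0.24). For this list camera gave adjusted p = 9.12e-07, and adjusted p = 0.36 with an estimated correlation. With day 56 sham in place of day 0 as the control, a comparison chosen after seeing the data, 0 of these T and NK genes and 0 of the B and plasma cell genes fell at day 3. The same change of control left 29 mitosis genes, 13 matrix genes and 8 mesothelial genes higher. Of 14 circadian clock genes 8 fell and 1 rose at day 3, 12 and 1 adjusted over the list alone, led by Ciart (-1.12 ± 0.26) and Per2 (a clock repressor, -0.97 ± 0.18). Camera gave it adjusted p = 5.19e-08, and adjusted p = 0.297 with an estimated correlation. With sham as the control, 7 clock genes were higher and 2 lower at day 3, with Ciart at 0.78 and Per2 at 0.79.

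Lists of development and differentiation were also read at day 3. Of 14 imprinted growth genes 5 rose and none fell over all genes, including Gatm (creatine synthesis, 2.01 ± 0.34), Grb10 (a growth factor receptor adaptor, 1.02 ± 0.12), Mest (0.84 ± 0.18) and Meg3 (0.80 ± 0.18). Adjusted over the list alone 6 rose and 2 fell. This group had adjusted p = 0.00423, and adjusted p = 0.16 with an estimated correlation. Of 31 lung branching and patterning genes 5 fell and none rose (3 higher and 5 lower adjusted over the list alone, list adjusted p = 0.13), the largest being Sox11 (-0.56 ± 0.12) and Etv5 (-0.49 ± 0.14). Of 13 fetal growth RNA-binding and HMG genes Dpysl3 rose (0.70 ± 0.15) and Sox11 fell, with 3 higher and 1 lower adjusted over the list alone and adjusted p = 0.105 for the list. In that list 4 rose and 1 fell without the 2 doubted arrays, 1 rose and 1 fell with sham as the control, and none passed in the lobes alone. None of 15 stem-cell-associated genes passed, and the smallest p belonged to Krt14 at 0.36 ± 0.11 and Abcg2 at -0.21 ± 0.07. Of 15 alveolar type II genes 1 fell, and of 13 alveolar type I genes 2 fell, Rtkn2 (-0.75 ± 0.19) and Hopx (-0.33 ± 0.09). Adjusted over the list alone 2 and 5 fell. The type II list had adjusted p = 3.09e-05, and adjusted p = 0.463 with an estimated correlation. The type I list had adjusted p = 4.02e-05, and adjusted p = 0.389 with an estimated correlation. Without the 2 doubted arrays 8 alveolar type I and 3 alveolar type II genes fell, 4 branching genes rose and 8 fell, 5 imprinted genes rose and 2 fell, and 2 stem-cell-associated genes rose. With sham as the control 4 alveolar type II genes fell, 2 branching genes rose and 6 fell, 3 imprinted genes rose, and 2 stem-cell-associated genes rose and 1 fell; in the lobes alone no alveolar or branching gene passed.

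In total 1336 genes differed at day 3 (limma, 792 higher and 544 lower), 1333 of them with 1 sign in all 3 regions. Passing the test makes 1 sign in all regions likely, so that agreement is no separate support. Centring each array on its own median gave 606 higher and 815 lower. The count was 739 and 723 without the day 0 cardiac lobe or whole lung, 749 and 664 without the day 3 cardiac lobe or whole lung, 628 without the region term and 335 in the lobes alone. Without the 2 doubted arrays, 2827 passed, including all 1336. Read in day 7 against sham, which shares no array with this comparison, 1238 of the 1336 genes (92.7%) kept their sign and 452 passed, against 69.7% with the same sign among the 18602 genes not called at day 3.

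**Figure D3:**
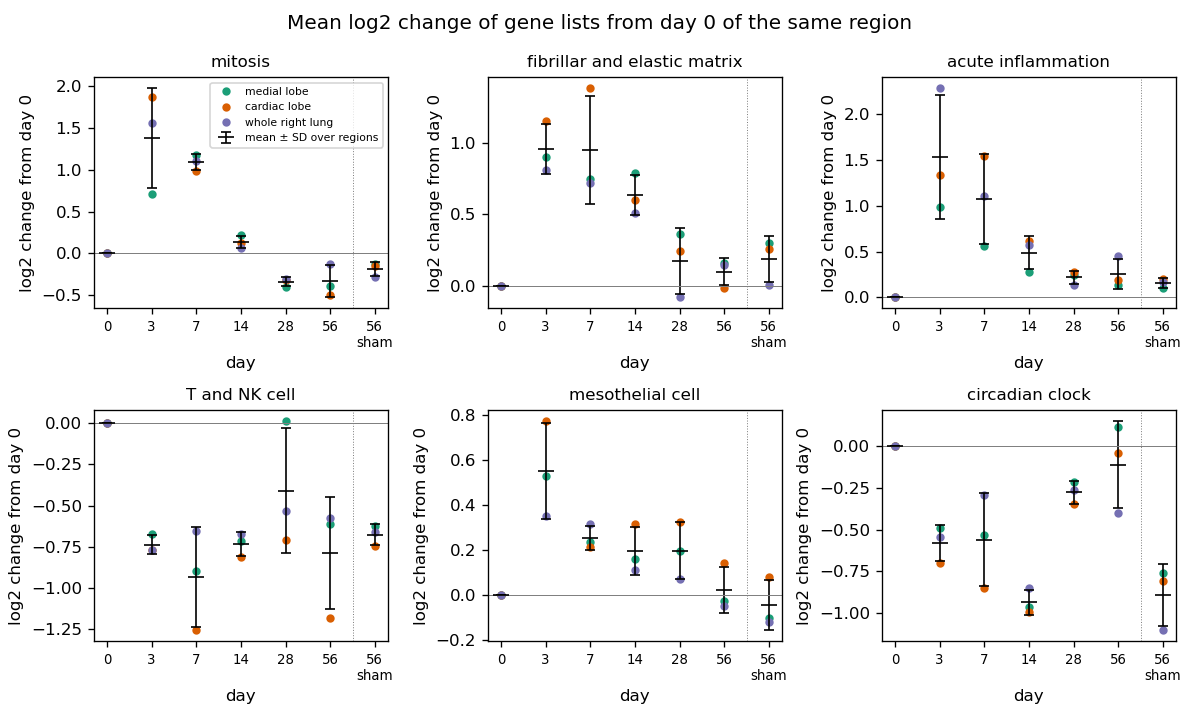
Mean log2 change of 6 gene lists from day 0 of the same region (y axis) by day (x axis, sham last), with points for the 3 regions and a black bar for their mean ± SD (n = 3). The mitosis list averaged 1.38 at day 3, 1.09 at day 7 and 0.14 at day 14, while the T and NK cell list lay at -0.74 at day 3 and -0.68 after sham surgery.

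At day 7 Saa3 (21.2-fold), Prg4 (16.3-fold), Arg1 (9.54-fold) and Timp1 (7.95-fold) were again higher than at day 0. They were joined by Clca1 (a secreted protein of mucous cells, 9.08-fold), Ccl24 (an eosinophil chemoattractant, 7.41-fold), Chil4 (a chitinase-like protein, 7.02-fold) and Mmp12 (macrophage elastase, 6.16-fold). The 8 largest falls were those of Lrat (log2 -2.05 ± 0.33), Ms4a1 (-1.92 ± 0.23), Depp1 (-1.91 ± 0.35), Ifi209 (-1.61 ± 0.26), Fcmr (an IgM Fc receptor, -1.61 ± 0.21), Cd3g (-1.59 ± 0.18), Ifi208 (-1.58 ± 0.27) and Sult1d1 (a sulfotransferase, -1.57 ± 0.41). Regions differed in size for some of these: the rise of Ccl24 ran from 0.36 to 5.83 and that of Arg1 from 0.83 to 5.18.

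Of 29 mitosis genes 26 rose at day 7, and 29 adjusted over the list alone, led by Ccna2 (1.63 ± 0.25), Prc1 (1.63 ± 0.23) and Top2a (topoisomerase II, 1.47 ± 0.23). The camera test gave adjusted p = 9.22e-22, and adjusted p = 0.325 with an estimated correlation. Of 27 DNA replication genes 15 rose, 20 adjusted over the list alone (adjusted p = 1.21e-10, and adjusted p = 0.345 with an estimated correlation). Of 26 matrix genes 16 rose, 19 adjusted over the list alone, with Tnc (tenascin C, 2.40 ± 0.31), Col1a1 (2.12 ± 0.40) and Eln (elastin, 1.91 ± 0.35) next to Timp1 (adjusted p = 7.68e-13, and adjusted p = 0.166 with an estimated correlation). Of 11 heat shock genes 6 rose, 7 adjusted over the list alone, led by Hspa1a (inducible HSP70, 2.25 ± 0.29) and Dnajb1 (0.84 ± 0.19). These genes had as a list adjusted p = 2.29e-05, and adjusted p = 0.146 with an estimated correlation. Of 14 T and NK cell genes 12 fell, all 14 adjusted over the list alone (adjusted p = 1.96e-11, and adjusted p = 0.166 with an estimated correlation). Of 14 ciliated cell genes 7 fell, 11 adjusted over the list alone, among them Hydin (-0.88 ± 0.25) and Dnah5 (an axonemal dynein, -0.75 ± 0.17). Its test gave adjusted p = 4.05e-06, and adjusted p = 0.468 with an estimated correlation. Without the 2 doubted arrays, 26 mitosis, 14 matrix and 5 heat shock genes rose, while 6 T and NK cell genes and 1 ciliated cell gene fell. Against sham in place of day 0, 1 T and NK cell gene and no ciliated cell gene fell, 2 heat shock genes rose and 2 fell, and Dnah5 lay at 0.016. In the lobes alone 15 mitosis and 9 DNA replication genes rose and 2 ciliated cell genes fell.

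Also at day 7, 8 of 12 B and plasma cell genes fell, and 8 adjusted over the list alone, with Cd79a (a B cell receptor subunit) at -1.43 ± 0.20 (list adjusted p = 8.27e-07, and adjusted p = 0.36 with an estimated correlation). Of 13 monocyte and interstitial macrophage genes 6 rose, and 8 rose and 1 fell adjusted over the list alone, with Retnla, a resistin-like protein of alternatively activated macrophages, at 1.42 ± 0.32 (adjusted p = 0.00825, and adjusted p = 0.508 with an estimated correlation). Of 12 mesothelial genes 5 rose, 6 adjusted over the list alone, with Wt1 at 1.14 ± 0.16 and Msln (mesothelin) at 0.52 ± 0.15 (adjusted p = 0.0141, and adjusted p = 0.473 with an estimated correlation). Of 17 acute inflammation genes 4 rose, 11 adjusted over the list alone (adjusted p = 1.61e-07, and adjusted p = 0.36 with an estimated correlation). Of 14 clock genes 8 fell, 10 adjusted over the list alone, with Bhlhe41 at -1.07 ± 0.16 and Nr1d1 at -0.89 ± 0.15 (adjusted p = 2.04e-06, and adjusted p = 0.355 with an estimated correlation). With sham as the control 4 B and plasma cell genes fell, 3 mesothelial genes rose, and 6 clock genes were higher and 1 lower, Bhlhe41 at 0.31 and Nr1d1 at 0.46. Without the 2 doubted arrays, 8 B and plasma cell genes and 5 clock genes fell, while 2 monocyte and 6 mesothelial genes rose.

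Among developmental genes at day 7, Sox9 (a regulator of distal lung buds, 0.62 ± 0.16) and Wnt5a (0.57 ± 0.16) rose, while Fgf18 (-0.60 ± 0.16) and Foxa2 (-0.49 ± 0.10) fell. These were the 4 of 31 branching and patterning genes that passed, over all genes and adjusted over the list alone, and the list had adjusted p = 0.138. Of 14 imprinted growth genes 4 rose and 1 fell, 5 and 3 adjusted over the list alone, led by Mest (1.21 ± 0.18), with adjusted p = 0.143 for the list. When the 2 doubted arrays were left out, Sox9 (0.40), Wnt5a (0.55) and Fgf18 (-0.40) no longer passed and Foxa2 (-0.37) did, and 2 imprinted genes rose and none fell. None of the 15 alveolar type II genes passed at day 7. Of 16 endothelial genes none passed against day 0 and 7 fell with sham as the control. Of 18 angiogenesis genes 5 fell and 1 rose against day 0, 6 and 1 adjusted over the list alone (adjusted p = 0.000952, and adjusted p = 0.473 with an estimated correlation). Against sham 10 angiogenesis genes fell and 1 rose, and without the 2 doubted arrays 3 fell and 1 rose.

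Day 7 had 1733 changed genes against day 0 (743 higher, 990 lower). Centring each array on its median gave 480 higher and 1473 lower. The count was 1052 without the 2 doubted arrays, with 922 of the 1733 genes in common, 1075, 547 and 491 without the day 0 medial lobe, cardiac lobe or whole lung, and 529 and 3888 without the day 7 cardiac lobe or whole lung. It was 424 without the region term, 34 when only the 6 arrays compared were fitted and 902 with sham as the control. Between days 3 and 7 only 13 genes passed (4 higher and 9 lower at day 7). Hspa1a rose 3.44-fold, Slc6a20a (an amino acid transporter) 1.81-fold and Cracr2a 1.57-fold, while Osr1 (a mesenchymal transcription factor, log2 -1.44 ± 0.19), B4galt6 (-1.13 ± 0.14) and Abca9 (-0.82 ± 0.13) fell. That count was 102, 4 and 0 without the day 3 medial lobe, cardiac lobe or whole lung, and 6 and 45 without the day 7 medial or cardiac lobe. It was 65 without the 2 doubted arrays.

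At day 14, 7 of 26 matrix genes were higher than at day 0, and the mitosis list averaged 0.14 ± 0.08 above it (log2, SD, n = 3). Prg4 was 8.24-fold, Spon2 (a matrix protein) 5.30-fold and Eln 3.93-fold higher than at day 0, while none of the mitosis genes (list adjusted p = 0.0743) and none of the DNA replication genes (list adjusted p = 0.0801) passed. The matrix genes that rose, 15 adjusted over the list alone, included Eln (1.97 ± 0.35), Timp1 (1.77 ± 0.23), Tnc (1.73 ± 0.31) and Lox (the collagen and elastin crosslinker, 1.31 ± 0.24). For this list camera gave adjusted p = 3.13e-14, and adjusted p = 0.166 with an estimated correlation. Only 1 matrix gene rose with sham as the control, Timp1, while Eln (1.40), Tnc (1.27), Lox (0.73) and Spon2 (0.28) did not pass; 14 matrix genes rose without the 2 doubted arrays and 4 in the lobes alone. The largest falls were in the circadian clock: Dbp (log2 -2.10 ± 0.22), Per2 (-2.03 ± 0.18) and Ciart (-1.93 ± 0.26). Arntl, which encodes BMAL1 and oscillates opposite to them, rose by 1.87 ± 0.14.

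Of 14 clock genes 10 fell and 1 rose at day 14, 12 and 2 adjusted over the list alone. Camera gave it adjusted p = 9.32e-19, and adjusted p = 0.146 with an estimated correlation. Of 14 T and NK cell genes 5 fell, 12 adjusted over the list alone (adjusted p = 6.45e-16, and adjusted p = 0.146 with an estimated correlation), and of 12 B and plasma cell genes 4 fell, 9 adjusted over the list alone (adjusted p = 2.03e-11, and adjusted p = 0.179 with an estimated correlation). In the lobes alone, no T and NK cell gene and 2 B and plasma cell genes fell at day 14. In all 240 genes differed from day 0 (99 higher, 141 lower; 70 and 161 after centring each array on its median). The count was 152, 95 and 136 without the day 0 medial lobe, cardiac lobe or whole lung, 83, 149 and 132 without those of day 14, 90 without the region term, 100 in the lobes alone, 59 with the mean of day 0 and sham as control and 811 without the 2 doubted arrays. With sham as the control, chosen after seeing the data, 13 genes passed at day 14, with none of the clock, T and NK cell or B and plasma cell genes among them. Dbp lay at 0.43 and Arntl at -0.23 against sham. Timp1 (1.65 ± 0.23), Prg4 (2.82 ± 0.44), Mmp2 (0.97 ± 0.16) and Igf1 (0.89 ± 0.14) were among the 10 that were higher, and Klf15 (-0.80 ± 0.10), Fgf10 (-0.57 ± 0.09) and Kcnj3 (-0.81 ± 0.13) were the 3 that were lower; these names were picked after their values were seen.

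From day 7 to day 14, 145 genes changed (43 higher, 102 lower). Of 29 mitosis genes 15 fell, 28 adjusted over the list alone, led by Ccna2 (-1.42 ± 0.25) and Top2a (-1.41 ± 0.23). This group had adjusted p = 8.79e-34, and adjusted p = 0.166 with an estimated correlation. Of 27 DNA replication genes 9 fell, 23 adjusted over the list alone, led by Rrm2 (-1.24 ± 0.20). As a list it had adjusted p = 9.7e-25, and adjusted p = 0.146 with an estimated correlation. Hspa1a (-1.71 ± 0.29) and the histone gene H1f1 (-1.50 ± 0.23) also fell, while Arntl (1.73 ± 0.14), Lrat (1.58 ± 0.33) and Fabp1 (a fatty acid binding protein, 1.35 ± 0.27) rose. The count was 39, 72 and 195 without the day 7 medial lobe, cardiac lobe or whole lung, 35, 5 and 50 without those of day 14, and 15 without the region term.

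At day 28 none of the 19938 genes passed against day 0 (limma; 1439 at an unadjusted p under 0.05, against 997 by chance). The smallest adjusted p, 0.115, belonged to Gbp5 (log2 -0.69 ± 0.11), Ifit3b (-1.04 ± 0.17) and Abcg2 (-0.42 ± 0.07). The count was 4 after centring each array on its median, 3 with the mean of day 0 and sham as control, 19 without the 2 doubted arrays and 37 against sham. From day 14 to day 28, 29 genes changed (9 higher, 20 lower): Dbp (1.98 ± 0.22), Per2 (1.24 ± 0.18) and Per3 (1.16 ± 0.18) rose, and Spon2 (-1.91 ± 0.34), Arntl (-1.63 ± 0.14) and Fam124b (-1.14 ± 0.17) fell. Of 14 clock genes 6 rose and 1 fell over that step, 11 and 2 adjusted over the list alone (adjusted p = 1.6e-15, and adjusted p = 0.146 with an estimated correlation). The count was 4 and 3 without the day 14 medial or cardiac lobe, 16 and 13 without those of day 28, 7 without the region term and 141 without the 2 doubted arrays.

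At day 56 after pneumonectomy 18 genes differed from day 0. Rbis rose (1.02 ± 0.16), and Cxcl9 (-1.63 ± 0.28), Ifi209 (-1.59 ± 0.26) and Ms4a1 (-1.31 ± 0.23) showed the largest of 17 falls. Of 14 T and NK cell genes 2 fell, Cd3g (-1.21 ± 0.18) and Cd3e (-0.88 ± 0.14), and 13 adjusted over the list alone (adjusted p = 7.02e-14, and adjusted p = 0.146 with an estimated correlation). The count of 18 was 0 without any 1 of 3 arrays (the day 0 cardiac lobe, the day 56 cardiac lobe and the day 56 whole lung), 10 and 3 without the day 0 medial lobe or whole lung, 1 without the region term and 7 without the 2 doubted arrays. It was 1 with every probe set, 6 without the dimmer genes, 41 with trended and robust variances, 4 in the lobes alone and 3 with the mean of day 0 and sham as control. Between days 28 and 56 no gene passed (limma; 1104 at an unadjusted p under 0.05), and the smallest p-values belonged to Angptl4 (-0.87 ± 0.13, adjusted p = 0.122), Abcg2 (0.38 ± 0.07, adjusted p = 0.605) and Cry1 (0.57 ± 0.11, adjusted p = 0.605).

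After sham surgery 76 genes differed at day 56 from day 0 (35 higher and 41 lower, or 26 and 47 after centring each array on its median). This comparison also spans 56 days of ageing, so an effect of the operation itself cannot be told apart. Spon2 rose 4.37-fold, Arntl 4.29-fold and the chaperone gene Hsph1 2.51-fold, while Dbp (-2.53 ± 0.22), Ciart (-1.90 ± 0.26) and Per2 (-1.76 ± 0.18) fell. Of 14 clock genes 9 fell and 1 rose, 10 and 2 adjusted over the list alone (adjusted p = 7.18e-18, and adjusted p = 0.146 with an estimated correlation). Of 11 heat shock genes 3 rose, 5 adjusted over the list alone: Hsph1 (1.33 ± 0.13), Hsp90aa1 (0.63 ± 0.08) and Hspd1 (0.39 ± 0.08). The camera test gave adjusted p = 6.47e-09, and adjusted p = 0.0607 with an estimated correlation. Of 14 T and NK cell genes 3 fell, 13 adjusted over the list alone: Cd3g (-0.88 ± 0.18), Cd3e (-0.75 ± 0.14) and Cd4 (-0.65 ± 0.12). These genes had as a list adjusted p = 4.65e-16, and adjusted p = 0.146 with an estimated correlation. The count was 26, 28 and 42 without the day 0 medial lobe, cardiac lobe or whole lung, 27 and 23 without the sham medial or cardiac lobe, 32 without the region term and 342 without the 2 doubted arrays.

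**Figure D4:**
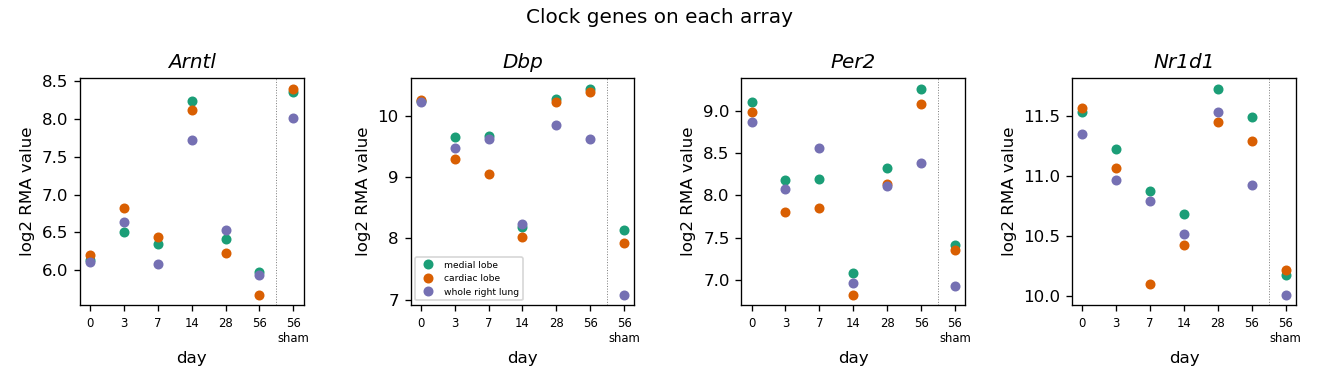
Log2 RMA value (y axis) of 4 clock genes on each of the 21 arrays by day (x axis, sham last), coloured by region. Arntl lay between 7.72 and 8.40 on the day 14 and sham arrays and between 5.68 and 6.83 on all others, and Dbp and Per2 were lowest on those same 6 arrays.

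At the matched time of 56 days, 67 genes differed between pneumonectomy and sham (14 higher, 53 lower after pneumonectomy). Dbp was 5.40-fold, Ciart 4.95-fold and Per2 by log2 1.68 ± 0.18 higher after pneumonectomy, while Arntl (log2 -2.38 ± 0.14), Spon2 (-2.31 ± 0.34) and Fam124b (-1.50 ± 0.17) were lower. Of 14 clock genes 8 were higher and 1 lower, 10 and 2 adjusted over the list alone (adjusted p = 7.98e-16, and adjusted p = 0.146 with an estimated correlation). Of 11 heat shock genes Hsph1 (-1.32 ± 0.13), Hsp90aa1 (-0.75 ± 0.08) and Hspd1 (-0.42 ± 0.08) were lower, 7 adjusted over the list alone. Its test gave adjusted p = 5.05e-11, and adjusted p = 0.0443 with an estimated correlation. Against day 0, no heat shock gene passed at day 56 after pneumonectomy, while Hsph1 (0.96 ± 0.13) and Hsp90aa1 (0.48 ± 0.08) rose at day 14. Day 14 and sham, both against day 0, shared 19 genes called higher and 34 called lower. The differences at 56 days may thus lie in the sham arrays and cannot be read as effects of lung removal alone. Fgf10 (a growth factor of lung mesenchyme, -0.67 ± 0.09) and Angptl4 (a lipoprotein lipase inhibitor, -1.08 ± 0.13) were also lower. None of the mitosis genes (list adjusted p = 0.0628) passed. The count was 36 without either of the medial and cardiac lobes after pneumonectomy, 29 and 30 without those after sham, 30 without the region term and 116 without the 2 doubted arrays.

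The cardiac and medial lobes differed in 18 genes over the 7 conditions (11 higher and 7 lower in the cardiac lobe, and 5 and 7 after centring each array on its median). Each of the 18 had 1 sign in at least 6 conditions, which passing the test also makes likely. Higher were Kcnab1 (a potassium channel subunit, 1.80-fold), Lum (the proteoglycan lumican, 1.74-fold), Grp (gastrin-releasing peptide, 1.69-fold), Itgb8 (1.64-fold), Igf1 (1.56-fold), Myo5a (1.45-fold), Prox1 (a transcription factor of lymphatic endothelium, 1.34-fold) and Itgae (1.28-fold). Lower were Cyp4a12b (log2 -1.92 ± 0.26), Lgals2 (-0.85 ± 0.14), Aldh3a1 (-0.77 ± 0.10), Adh7 (an alcohol dehydrogenase, -0.63 ± 0.09), Ngb (-0.41 ± 0.07), Slc16a11 (-0.38 ± 0.07) and Eps8l2 (-0.28 ± 0.04). Of 11 club cell genes none passed over all genes and 6 were lower adjusted over the list alone (adjusted p = 1.94e-08, and adjusted p = 0.179 with an estimated correlation). Of 14 ciliated cell genes 0 passed and 11 were lower adjusted over the list alone (adjusted p = 1.34e-13, and adjusted p = 0.292 with an estimated correlation). The count was 3 to 10 without any 1 of 15 arrays, the lowest without the day 3 cardiac lobe, and 40 without the 2 doubted arrays. It was 179 with every probe set (28 higher, 151 lower), 6 without the dimmer genes and 11 with trended and robust variances.

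The mean of the lobes differed from the whole lung in 5794 genes (4042 higher and 1752 lower in the lobes; 7034 and 636 after centring each array on its median). The largest differences downward were in small nucleolar RNA genes: Snord118 (log2 -3.84 ± 0.54), Snora33 (-2.90 ± 0.32) and Snord22 (-2.59 ± 0.23). Upward they were Prmt8 (2.46-fold), Mmrn1 (2.34-fold) and the potassium channel gene Kcnj2 (2.30-fold). Of 16 endothelial genes 15 were higher in the lobes, and 15 adjusted over the list alone (adjusted p = 6.22e-08, and adjusted p = 0.389 with an estimated correlation), such as Emcn (0.72 ± 0.15) and Vwf (0.66 ± 0.13). Of 15 alveolar type II genes 12 were higher, and 12 adjusted over the list alone, such as Etv5 (0.84 ± 0.08) and Lamp3 (0.74 ± 0.10). For this list camera gave adjusted p = 1.26e-08, and adjusted p = 0.34 with an estimated correlation. Of 12 mesothelial genes 7 were lower, 9 adjusted over the list alone, such as Muc16 (-0.63 ± 0.11) and Wt1 (-0.52 ± 0.09). Camera gave it adjusted p = 2.64e-05, and adjusted p = 0.292 with an estimated correlation. The whole lung arrays also had the higher small RNA values given above, the count was 3860 without the day 14 whole lung, and 5244 of the 5794 genes passed without the 2 doubted arrays.

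No gene passed for a difference in early response between the cardiac and medial lobes (limma interaction, smallest adjusted p = 0.964). At an unadjusted p under 0.05 there were 868, against 997 by chance. Conditions of a phase stood in for replicates, so differences between the days of a phase add to the error. For this comparison the simulation recovered 11 of 100 genes shifted by log2 0.5 and 63 of 100 shifted by log2 1, so real differences could be missed. The smallest p-values belonged to Pappa (1.22 ± 0.24), Ccdc34 (0.72 ± 0.14) and Il6 (1.48 ± 0.30). The count was 438 without the day 3 cardiac lobe array, which leaves the doubted day 7 array as the only early cardiac sample, 1 without the day 3 or day 7 whole lung and 0 without any other array.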

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

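The tests of the clock, of tissue composition and of array quality for the macrophage and mesothelial genes were chosen after the results were seen. So were the list of serous cavity macrophage genes and the choice to leave out the 2 doubted arrays. A search of 21 groups of 7 arrays for single arrays far from the rest would single out about 1 in 20 groups by chance.

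The day 7 cardiac lobe array lay far from the other cardiac arrays in interquartile range (3.55, others 3.73 to 3.86) and in the skeletal muscle list (6.10, others 5.57 to 5.75). The day 28 cardiac lobe array lay far from the others in the adipocyte list (8.90, others 6.09 to 6.68), with Ucp1, the uncoupling protein of brown fat, at 10.75. The day 28 whole lung array lay far from the others in the skeletal muscle list (7.00, others 5.62 to 5.81), with Acta1 at 9.88 and Ckm at 9.81. Among 13767 probe sets with no or several genes listed, 46 changed at day 3 and 60 at day 7, against 2 after sham surgery. Of the 19938 genes, 1336 and 1733 changed on those days. Between regions, 186 of these probe sets differed for cardiac against medial and 2227 for lobes against whole lung.

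The early response (days 3 and 7 against day 0 and sham) differed between the cardiac and medial lobes in 12 lists by camera. Medians of cardiac minus medial were 0.65 for monocyte and interstitial macrophage (adjusted p = 0.00104, and adjusted p = 0.473 with an estimated correlation), 0.51 for acute inflammation (3.1e-05, 0.389), 0.50 for mitosis (6.6e-09, 0.503), 0.41 for fibrillar and elastic matrix (0.000173, 0.473), 0.34 for DNA replication (1.6e-08, 0.389), 0.24 for smooth muscle (0.0107, 0.503) and 0.15 for mast cell and basophil genes (0.0149, 0.402). They were -0.24 for alveolar type II (0.00306, 0.611), -0.26 for branching and patterning (0.00188, 0.34), -0.37 for alveolar type I (1.74e-06, 0.297), -0.43 for endothelial (6.65e-07, 0.393) and -0.43 for angiogenesis genes (0.000919, 0.465). Leaving out the 2 doubted arrays left the day 3 array as the only early cardiac sample, set against days 3 and 7 of the medial lobe. Lobe and day cannot be told apart in that fit, so only its medians are given. They were 0.98 for mitosis, 0.59 for DNA replication, 0.51 for smooth muscle, 0.20 for matrix and -0.23 for alveolar type I genes. For the angiogenesis, branching and mast cell lists they were -0.22, -0.09 and 0.06, and for the ciliated and mesothelial lists 0.32 and 0.32.

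Clock genes differed from day 0 at day 14 and after sham surgery. An effect of lung removal cannot account for the shift after sham surgery, where no lung was removed and 10 clock genes passed. For the shift at day 14 it could not be tested, because that day has no sham array. RNA or array quality is argued against, since 12 passed at day 14 in the lobes alone. A candidate explanation left open is tissue collected at another time of day: 0 of 14 clock genes passed between day 14 and sham (limma). The labels give no time of day, and no other biological explanation was tested.

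The whole right lung arrays differed from the lobes in 5794 genes. RNA or array quality may account for part of this: across genes, lobes minus whole (day 7 left out) correlated at r = -0.512 with cardiac minus medial at day 7, where the cardiac array had high small RNA values, against -0.213 to 0.221 on the other days. More airway, pleura and vessel wall in the whole lung cannot be told apart: 3 of 4 list medians lay below 0 (club -0.11 ± 0.19, ciliated -0.08 ± 0.06, mesothelial -0.21 ± 0.07), but smooth muscle lay at 0.16 ± 0.05 (standard errors over genes). A true difference between the lobes and the rest of the lung also stays open.

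Macrophage and mesothelial genes rose at days 3 and 7. RNA or array quality is argued against for the mesothelial genes, of which 8 rose at day 3 in the lobes alone and 6 at day 7 without the 2 doubted arrays, but could not be told apart for the macrophage genes. Of these, 3 monocyte genes rose at day 3 in the lobes alone against 7 on all arrays (median log2 0.63 and 0.92), and at day 7 2 rose without the 2 doubted arrays against 6 with them (median 0.50 and 0.61), while 9 rose at day 3 and 5 at day 7 with sham as the control. Cells of the pleural cavity on or in the lobes may contribute: 6 of 9 measured serous cavity macrophage genes were higher at day 3 at an unadjusted p under 0.05 (median 0.97), of which F10 (1.36 ± 0.37) and Hdc (0.97 ± 0.20) passed over all genes and Timd4 (-0.05 ± 0.33), Garnl3 (0.06 ± 0.08) and Lyz1 (-0.29 ± 0.19) did not. The serous cavity list was chosen after the results were seen. At the same unadjusted cutoff, 3903 of all 19938 genes differed at day 3, in either direction. Lung macrophages and mast cells express some of the serous cavity genes, and a response within the lung tissue stays open.

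Other groupings of the arrays were counted for each comparison. For the 7 conditions 1 of 100 regroupings gave as many genes, the real one with 1547, and the highest other gave 298. Condition labels were permuted within each region. If the regions of a condition shared animals, the regroupings would also break up differences between animals, so these differences are not excluded. A chance arrangement of region labels is unlikely to give the counts for cardiac against medial (1 of 64 swaps, 18 genes, highest other 1). The same holds for lobes against whole lung (1 of 100, 5794 genes, highest other 124). These regroupings cannot separate the region from handling that differed by region. For the difference in early response the real count was 0 (limma, 868 at an unadjusted p under 0.05), so 64 of 64 swaps necessarily gave as many. Comparisons of 3 with 3 arrays have 10 splits, too few for a share under 0.05. The real count and the highest other were 1336 and 0 at day 3, 1733 and 1 at day 7, 240 and 0 at day 14, 18 and 0 at day 56, 76 and 0 after sham, 67 and 1 for day 56 against sham, 13 and 7 for day 7 against day 3, 145 and 0 for day 14 against day 7, and 29 and 0 for day 28 against day 14. In each of these 1 split, the real one, gave as many. At day 28 against day 0 and at day 56 against day 28 the real count was 0, so 10 of 10 splits gave as many.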

How the results depend on the processing

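Leaving out the 2 doubted arrays and using sham as the control for earlier days were chosen after seeing the data. The alternatives changed how many genes passed more than their direction: named genes that had passed changed sign only with another control. The causes of the changes in count were not tested, except that the lobes alone and the 6-array fits use fewer arrays and leaving out the dimmer genes tests fewer genes. Background signal was not given in the table, so what signal over background limits was not tested.

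Without the region term (no replicate block) the counts were 628 at day 3, 424 at day 7, 90 at day 14, 1 at day 56, 32 after sham, 30 for day 56 against sham, 0 for day 7 against day 3 (limma), 15 for day 14 against day 7, 7 for day 28 against day 14 and 671 for any difference. With every probe set they were 1 at day 56, 46 after sham, 7 for day 7 against day 3 and 179 for cardiac against medial. Without the dimmer genes (those under the median by mean) they were 829 at day 3, 1072 at day 7, 6 at day 56, 46 after sham, 82 for day 14 against day 7 and 6 for cardiac against medial. With trend and robust moderation they were 41 at day 56 and 11 for cardiac against medial. With arrays centred on their medians they were 4 at day 28 and 84 for day 14 against day 7. In the lobes only they were 335 at day 3, 100 at day 14, 4 at day 56, 6 for day 7 against day 3, 37 for day 14 against day 7, 2 for day 56 against day 28 and 544 for any difference. With only the 6 arrays compared, day 7 gave 34. With the mean of day 0 and sham as control they were 59 at day 14, 3 at day 28 and 3 at day 56. With sham as control they were 902 at day 7, 13 at day 14 and 37 at day 28. Without the 2 doubted arrays they were 2827 at day 3, 1052 at day 7, 811 at day 14, 19 at day 28, 7 at day 56, 342 after sham, 116 for day 56 against sham, 65, 89 and 141 for the steps to days 7, 14 and 28, 40 for cardiac against medial and 2501 for any difference. Of the 532 list tests 1 passed with an estimated correlation, against 229 with the preset value.

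With 1 array left out, the lone array of a region and condition being assumed to vary like the rest, the counts ranged from 1032 to 1933 for any difference, 664 to 1272 at day 3, 491 to 3888 at day 7, 83 to 152 at day 14, 0 to 1 at day 28, 0 to 27 at day 56, 23 to 89 after sham, 29 to 75 for day 56 against sham, 0 to 102 for day 7 against day 3, 5 to 195 for day 14 against day 7, 3 to 40 for day 28 against day 14, 0 to 1 for day 56 against day 28, 3 to 20 for cardiac against medial, 3860 to 8113 for lobes against whole lung and 0 to 438 for the difference in early response.

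With the mean of day 0 and sham as control, Per3 at day 3 lay at 0.03, and Dbp and Per2 at day 7 at 0.47 and 0.10. With sham as control, values at day 3 were 0.40 for Cxcl9, 0.78 for Ciart, 0.79 for Per2, 0.55 for Bhlhe41 and 0.86 for Per3. At day 7 they were 0.016 for Dnah5, 0.31 for Bhlhe41, 0.46 for Nr1d1, 1.74 for Dbp, 0.98 for Per2, -0.57 for Hsph1 and -0.12 for Hspb1, and at day 14 0.43 for Dbp, -0.23 for Arntl, -0.37 for Hsph1 and -0.16 for Hsp90aa1. Of the named values that passed, 150 of 285 no longer passed without the region term, 134 of 285 in the lobes alone, 105 of 184 with only the 6 arrays compared, 89 of 215 with sham as control, 57 of 222 with the pooled control, 45 of 414 without the 2 doubted arrays, 34 of 414 after centring, 13 of 414 with trend and robust moderation, 3 of 318 without the dimmer genes and 2 of 414 with the mean of a gene's probe sets. With 1 array left out this was so for 1019 of 4419.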

Other observations

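The interferon response list was read at days 3, 7, 14, 28 and 56 after pneumonectomy against day 0. Counts with sham as the control are given for days 3, 7 and 14 only. The comparison of day 56 after pneumonectomy with sham was run but is not given for this list. The values printed for days 28 and 56 therefore stand against day 0 alone. Of 14 measured genes, Ifit1 (an interferon-induced antiviral gene, -0.89 ± 0.14) fell at day 56 after pneumonectomy, and 7 adjusted over the list alone, with adjusted p = 7.74e-08 for the list and adjusted p = 0.166 with an estimated correlation. Ifit1 no longer passed at day 56 without the 2 doubted arrays (-0.78), without the region term, in the lobes alone, or without any 1 of 5 of the 6 arrays compared. At day 28 none passed, with Ifit1 at -0.68 ± 0.14 (adjusted p = 0.202), 4 were lower adjusted over the list alone, and the list had adjusted p = 2.46e-07, and adjusted p = 0.166 with an estimated correlation. At day 14, 2 fell, Ifit3 (-0.75 ± 0.16) and Ifit1 (-0.68 ± 0.14), and 5 adjusted over the list alone (adjusted p = 0.000264, and adjusted p = 0.34 with an estimated correlation); with sham as the control none fell. At day 7, Oasl2 rose (0.40 ± 0.12) and 3 fell, 2 and 4 adjusted over the list alone (list adjusted p = 0.86). That count was 1 higher and 2 lower without the 2 doubted arrays, 2 higher and none lower against sham, and 3 higher and 4 lower in the lobes alone. At day 3, 3 rose and 2 fell, 4 and 3 adjusted over the list alone (list adjusted p = 0.448), while against sham 3 rose and none fell, and in the lobes alone 1 rose.

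Other lists at day 3 included those of vessels and alveolar macrophages. Of 18 angiogenesis genes 4 fell and Mmp14 rose (1.36 ± 0.21), and 8 fell and 2 rose adjusted over the list alone, with Sphk1 at -0.89 ± 0.15 and Esm1 at -0.86 ± 0.17 (adjusted p = 0.000587, and adjusted p = 0.472 with an estimated correlation). Of 16 endothelial genes none passed over all genes and 2 were lower adjusted over the list alone (adjusted p = 0.00014, and adjusted p = 0.511 with an estimated correlation). Against sham in place of day 0, 9 endothelial genes fell, and 7 angiogenesis genes fell and 1 rose. After leaving out the 2 doubted arrays 3 endothelial genes fell, and 6 angiogenesis genes fell and 1 rose. Of 12 alveolar macrophage genes 3 fell at day 3, Krt79 (-0.78 ± 0.12), Siglecf (-0.44 ± 0.11) and Itgax (-0.40 ± 0.11), and 6 adjusted over the list alone (adjusted p = 0.00699, and adjusted p = 0.465 with an estimated correlation). Against sham 1 alveolar macrophage gene rose and 1 fell, and without the 2 doubted arrays 6 fell. Of 13 retinoic acid pathway genes 4 rose, including Stra6 (the retinol uptake receptor, 0.60 ± 0.14) and Rdh10 (0.49 ± 0.09), and 4 rose and 3 fell adjusted over the list alone (list adjusted p = 0.434). Against sham 3 of these rose, and without the 2 doubted arrays 4 rose and 2 fell.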
